A study of Mus musculus with 8 samples.

How the data were processed

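RNA from the palatal shelves of 8 mouse embryos at embryonic day 13.5 was sequenced, and per the labels the control and mutant palates were lysed individually. The palatal shelves are the paired outgrowths of the maxillary processes that later fuse to form the secondary palate. Per the labels' protocols, the shelves were dissected under a microscope and frozen, total RNA was extracted with a column kit, and libraries were made with the Illumina TruSeq RNA kit v2 after selection with oligo(dT). The strain label is C57BL/6 for all embryos. The genotype label put 4 embryos in the Pax9 null group, 2 in the wild-type group and 2 in the heterozygote group. The replicate numbers within a group follow the order of the samples and name a library only. Each sample title holds the number 44 or 56, called the title number here, and nothing in the labels says whether it stands for a litter or how embryos were assigned to library batches. Null 1, null 3, wild type 1 and heterozygote 1 carry 56, and the other libraries carry 44. The protocol text on a drug given to pregnant females does not apply to these samples, whose treatment label is not applicable.

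The deposited table holds FPKM values, that is fragment counts scaled by gene length and by the total of assigned fragments, for 19083 Ensembl genes in the 8 libraries. Per the submitters' processing notes, the reads were aligned with Novoalign 2.08.03, the genome build was mm10, and DESeq2 was used, with no version stated. The counting program, the gene annotation and the filters behind the 19083 genes are not given in the sources used here. The kit does not mark the strand of the RNA, so reads of a gene and of an overlapping antisense gene cannot be separated. Reads of genes that share exons on the same strand can likewise have been split or dropped by the authors' counting.

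The FPKM of low genes moved in whole steps, which gave the depth of each library. Each of the 19083 genes came out as whole reads in all 8 libraries, within a tolerance of 0.03 of a read, and the 99th percentile of the distance to a whole number was 6.19e-06. The recovered reads assigned to genes were 48760552, 37848574, 51210254 and 37069101 in null libraries 1 to 4, 45849675 and 38096874 in wild-type libraries 1 and 2, and 38749441 and 38428642 in heterozygote libraries 1 and 2. The product of the reads and the worth of 1 read differed between libraries by no more than the span from 0.9999 to 1.0 of that in null library 1, so the FPKM values were scaled to the total of gene reads. To check for a library deposited more than once, the recovered reads of pairs of libraries of the same genotype were compared by chi-square, which gave between 12.2 and 49.3 per degree of freedom. No pair agreed within sampling noise, so each library was counted as 1 sample.

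Gene symbols, positions, exon overlaps, GC content and exon lengths came from GENCODE release M21 on GRCm38, the assembly that mm10 names. In it, 18752 of the identifiers were found and 331 were not; the latter were tested without a position. Coordinates are 1-based.

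Genes with an FPKM of at least 1 in 2 or more of the 8 libraries were tested, which left 13600. Values were analysed as log2(FPKM + 0.5) with limma 3.58.1 in R 4.3.3, using empirical Bayes moderation with a mean-variance trend and Benjamini-Hochberg adjustment over all tested genes. A gene was called changed at an adjusted p under 0.05. All p-values from limma are two-sided. Fold changes are on the log2(FPKM + 0.5) scale, which understates the change of low genes. The main comparison set the 4 null libraries against the 4 controls, which are the wild types and the heterozygotes together, in a fit with 2 groups. A fit with 3 groups gave null against wild type, null against heterozygote and heterozygote against wild type. Plots and summaries were made in Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.

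Of 31 gene lists for palate pathways and for cell types that a dissection of the palate can hold, 30 had at least 3 measured members and were tested with camera at a preset correlation of 0.01, with adjustment over the lists. The list of salivary gland, thyroid and pituitary markers had too few measured members and was not tested. Each list was tested again with an estimated correlation between genes, and with fry. Fry asks whether the genes of a list move one way, without a comparison with other genes. Its mixed form, named as such where used, counts changes in either direction. Beside the number of members past the threshold over all tested genes, the number adjusted over the list alone is given.

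Of the deposited table's columns, 0 belonged to other samples. The lists, the comparisons, the tests of genes and lists in them and the rule for named genes were fixed before the data were examined; further tests chosen after the results were seen are named as such in the closing section. The rule names Pax9, the 12 largest rises and the 12 largest falls among called genes whose null and control libraries do not overlap, up to 4 called members of each list, and the 2 most abundant members of a list with fewer than 2 calls. It also names up to 5 genes per direction in each other comparison, and it leaves out predicted genes. List members named because they passed only over the list alone, and called genes named in the closing section outside the rule, were chosen after their values were seen. The result for 1 gene is not reported here.

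The procedure was tested on simulated data for the comparison of null with control over 13600 genes. It recovered 74.2% of simulated changes of 0.5 log2 units, 94.0% of changes of 1 unit and 97.0% of changes of 2 units, with 10 false calls. The simulated noise was drawn independently for each gene, with its spread taken around the means of the 3 genotypes. It held no variation shared between genes and no difference between wild types and heterozygotes. The shares therefore apply to data cleaner than these. Alternatives fixed beforehand were other pseudocounts, other filters, quantile and median scaling, the title number as a block, robust moderation, the level of Y-linked genes as a covariate, a fit with 3 groups, the embryos of each title number alone, other correlations for the lists and leaving out each library. Alternatives chosen after seeing the data were limma-voom on the recovered whole reads, the main axis of variation within null and control as a covariate, the side of that axis as a block and each side alone, and removal of a GC trend from each library by lowess with a span of 0.3. That axis was taken after the null mean and the control mean of each gene were subtracted. It can therefore hold a difference between wild types and heterozygotes. The sides of the axis were read off the expression values and are not groups of the study.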

Results

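Poly(A)-selected RNA from the palatal shelves of 8 mouse embryos at embryonic day 13.5 was compared between Pax9 null embryos (n = 4) and controls (n = 4, of which 2 were wild type and 2 heterozygous). Pax9 is a paired-box transcription factor needed for the growth and elevation of the shelves and for tooth development. Each library held between 37069101 and 51210254 reads assigned to genes. The labels do not say whether embryos share a litter, so the p-values measure the spread between these 8 embryos.

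Pax9 RNA was lower in every null library than in every control library. Its FPKM was 8.49, 7.19, 9.81 and 10.3 in null libraries 1 to 4, against 35.8 and 27.2 in the wild types and 30.1 and 26.2 in the heterozygotes. The mean of 8.95 ± 1.40 (SD, n = 4) in null compared with a control mean of 29.8 ± 4.29 (SD, n = 4), and was 28.4% of the wild-type mean. The log2 change was −1.68 with a standard error of 0.13 (limma, adjusted p = 0.000556). Pax9 (ENSMUSG00000001497) lies on chromosome 12 from 56691767 to 56712822 on the plus strand in mm10. The labels do not state which exons the mutation removes, and the value covers the whole gene, so the remaining reads do not show whether intact transcript was made. Under the alternatives for the Pax9 level, the log2 change within the embryos of title number 44 alone was −1.58 (limma, adjusted p = 0.217), and within null 1, null 2 and the wild types alone it was −1.93 (adjusted p = 0.0559). Over all alternatives it lay between −1.93 and −1.44, with an adjusted p between 0.000262 and 0.217.

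The main comparison asked which transcripts differ between palatal shelves with and without Pax9. Loss of Pax9 went with lower RNA of the homeobox factor Msx1, which acts in the anterior palatal mesenchyme, and with higher RNA of the zinc-finger factor Osr2 and the homeobox factor Dlx6. Msx1 fell from 78.2 ± 17.3 FPKM in controls to 33.5 ± 7.85 in null (SD, n = 4 each), a log2 change of −1.21 with a standard error of 0.18. Osr2 rose from 96.0 ± 17.0 to 160 ± 4.47 FPKM, a log2 change of 0.75 with a standard error of 0.11. The largest fall among the named genes was that of Hs3st2, a heparan sulfate sulfotransferase, from 2.84 ± 0.37 to 0.31 ± 0.17 FPKM. The largest rises among them were those of Stfa1, a cysteine protease inhibitor of the stefin A family, from 0.60 ± 0.32 to 2.59 ± 0.55 FPKM, and of Dlx1as, a long noncoding RNA antisense to Dlx1, from 3.18 ± 0.41 to 9.95 ± 0.56 FPKM.

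In total 57 of 13600 genes changed, 31 higher and 26 lower in null (limma, adjusted p under the threshold), and 972 had an unadjusted p under 0.05. All 57 had null values that did not overlap the control values, as did 698 tested genes or 5.13%, where chance gives 2.86%. The absolute log2 change of the called genes had a median of 0.68 and ranged from 0.29 to 2.06, with 14 genes at 1 or more. The median change of all tested genes was −0.01. Akap2 and Pakap were both counted among the lower genes, with log2 changes of −0.40 and −0.41. In the annotation 84.4% of the exons of Akap2 are shared with Pakap on the same strand, so these 2 calls need not be separate changes. For changed genes, null against control, leaving out 1 library moved the count to 16 without wild type 1, 17 without null 2, 21 without null 1, 28 without wild type 2 or heterozygote 1 and 29 without null 3. It was 268 with the main axis of variation within null and control as a covariate, 176 with the side of that axis as a block, 2 and 3 within either side alone, 134 after removal of a GC trend, 0 and 4 within title numbers 44 and 56 alone, and 35 among genes with a mean FPKM of at least 5.

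**Figure D1:**
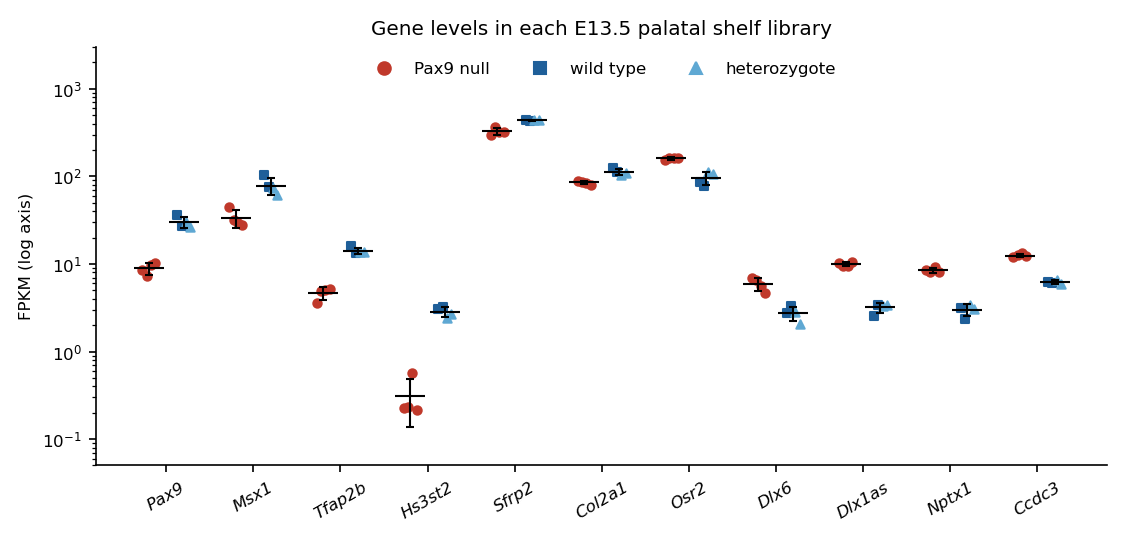
FPKM on a log axis of 11 genes in each library; circles are Pax9 null embryos (n = 4), squares wild types (n = 2) and triangles heterozygotes (n = 2), and horizontal bars with whiskers are the mean ± SD of the 4 null and of the 4 control libraries. Pax9 lies between 7.19 and 10.3 in null and between 26.2 and 35.8 in controls, and for each of the 11 genes the null and control values do not overlap.

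Among the other large falls were genes of several kinds. Tfap2b, a transcription factor of neural crest derivatives, fell from 14.2 ± 1.18 to 4.66 ± 0.74 FPKM, a log2 change of −1.51. Adcy8, a calcium-stimulated adenylyl cyclase, fell by 1.48 on the log2 scale and Grik3, a kainate-type glutamate receptor subunit, by 1.19. The neural adhesion molecule Cntn6 fell by 1.20, the sulfate donor synthase Papss2 by 1.03 and the calmodulin regulator Pcp4 by 0.81. Tmem30b, a subunit of lipid flippases, fell by 0.77. Papss2 makes the sulfate donor that sulfotransferases such as Hs3st2 use. In the annotation 23.7% of the exons of Pcp4 are shared with a second locus named Igsf5 on the same strand, and reads there can have been assigned to either.

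Of the genes that rose, Nptx1, a neuronal pentraxin, went from 2.99 ± 0.46 to 8.45 ± 0.56 FPKM, a log2 change of 1.37. Ccdc3, a secreted protein, rose from 6.21 ± 0.28 to 12.5 ± 0.58 FPKM, although 69.1% of its exons overlap a predicted gene on the other strand, which this kit cannot separate. Dlx6os1, a noncoding RNA of the Dlx5 and Dlx6 locus, rose by 1.18 on the log2 scale, from 0.57 ± 0.06 to 1.94 ± 0.37 FPKM. Dlx1as shares 20.6% of its exons with Dlx1 on the other strand, and Dlx1 itself had a log2 change of 0.01 with a standard error of 0.06. Smaller rises were those of the adhesion molecule Cntn3 at 0.84, Rgs5, a G-protein regulator known from pericytes, at 0.82, the potassium channel gene Kcnt2 at 0.79, the imprinted gene Magel2 at 0.75 and Brinp3, expressed in neurons, at 0.75.

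**Figure D2:**
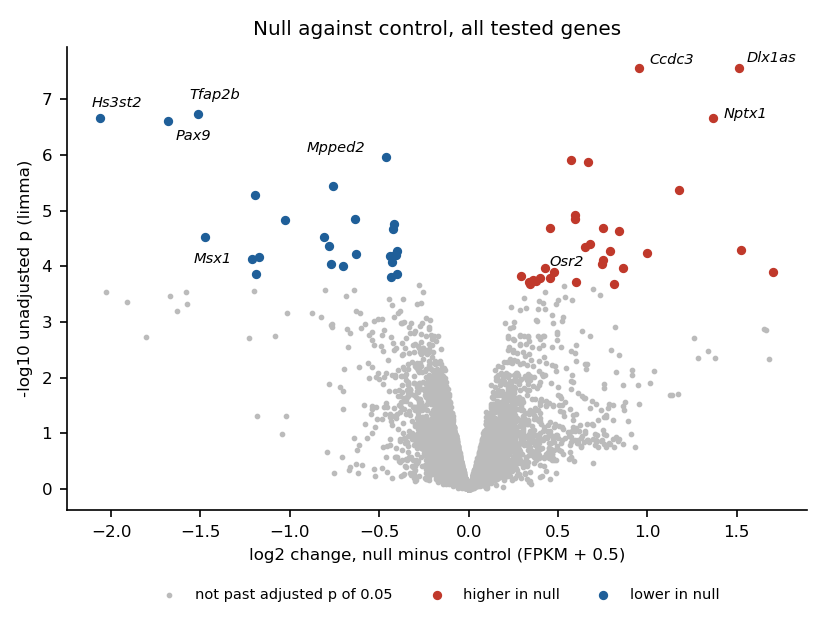
Each point is 1 of 13600 tested genes, with the log2 change of null minus control on log2(FPKM + 0.5) on the horizontal axis and −log10 of the unadjusted limma p on the vertical axis. The 31 genes higher in null are red and the 26 lower in null are blue, and Pax9, Hs3st2 and Tfap2b are at the upper left with log2 changes of −1.68, −2.06 and −1.51.

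Of the 29 called genes named by the rule, 11 stayed past the threshold in each of the 8 leave-outs: Pax9, Dlx1as, Nptx1, Ccdc3, Dlx6os1, Hs3st2, Tfap2b, Cntn6, Papss2, Synpo2 and Mpped2. The other 18 lost it in at least 1, with adjusted p values of at most 0.174, and all kept their direction. Msx1 passed only without null 1 or heterozygote 2, and its adjusted p reached 0.102 in the other 6 leave-outs. Osr2 passed without wild type 2, heterozygote 1 or heterozygote 2 and reached 0.104 in the other 5, and Dlx6 passed without wild type 2, null 4 or heterozygote 2 and reached 0.0984 in the other 5. Sfrp2 passed only without null 2 and reached 0.115, and Col2a1, Rgs5, Kcnt2 and Brinp3 passed in none of the 8, with 0.13, 0.174, 0.0867 and 0.116 at most. Osr2 and Sfrp2 also missed the threshold after removal of the GC trend, at adjusted p values of 0.0504 and 0.055. Their log2 changes before and after were 0.75 and 0.77 for Osr2, with standard errors of 0.11 and 0.15, and −0.43 and −0.41 for Sfrp2, with standard errors of 0.06 and 0.08. For the remaining called genes, Adcy8 lost the threshold without null 2, wild type 2 or null 3, Cntn3 without wild type 1, null 2 or null 3, Magel2 without wild type 1 or null 2, and Pcp4 without null 1, wild type 1, null 2 or heterozygote 1, with adjusted p values of at most 0.0613, 0.0659, 0.057 and 0.0695. Stfa1 and Egln3 lost it without any of null 1, null 2, null 3, wild type 1 and heterozygote 1, at most 0.0973 and 0.06. Matn4 passed only without null 4 or heterozygote 2, Spp1 only without null 2 or null 4, Grik3 only without null 3 or heterozygote 2 and Tmem30b only without wild type 1 or heterozygote 2, with 0.0898, 0.0825, 0.142 and 0.104 at most. Over all alternatives the adjusted p of Osr2 lay between 0.000871 and 0.707 and that of Sfrp2 between 0.0139 and 1.0.

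Among palatal mesenchyme transcription factors, 2 of 30 tested genes rose (Osr2 and Dlx6), 1 fell (Msx1) and 27 did not pass over all genes. Adjusted over the list alone, 4 were higher and 3 lower. The members added by that adjustment were Dlx5, at 18.7 against 10.4 FPKM, and Barx1, at 328 against 269 FPKM, both higher, and Hand2, at 0.83 against 4.07 FPKM, and Foxf1, at 36.7 against 49.1 FPKM, both lower. The list as a whole had a median log2 change of 0.02 (camera adjusted p = 0.238). Both values look for a shift one way and can miss a list whose members move both ways. By the mixed form of fry its adjusted p was 3.32e-06. That form also passed for other lists, among them the BMP (adjusted p = 0.0058), Hedgehog (0.0297) and osteogenic (0.00134) lists. Anterior palate markers were lower as a group, with 1 of 6 members past the threshold over all genes (Msx1) and 2 lower, Msx1 and the growth factor Bmp4, adjusted over the list alone. Their median was −0.19 (camera adjusted p = 0.0234, and adjusted p = 0.29 with an estimated correlation). Shox2, another anterior factor, was at 51.1 FPKM in null and 43.6 in controls and did not pass (adjusted p = 0.768). Posterior palate markers had 0 of 5 members past the threshold over all genes and 1, Barx1, adjusted over the list alone (median 0.03, camera adjusted p = 0.307); Mn1, the other abundant one, was at 33.0 against 34.5 FPKM.

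Extracellular antagonists of Wnt signalling were lower as a group, with 11 of 14 below 0 in point estimate and 3, Dkk1, Dkk2 and Kremen1, above it. Sfrp2, the most abundant of them and a binder of Wnt ligands, fell from 439 ± 5.74 to 327 ± 28.3 FPKM, a log2 change of −0.43, and was the 1 member of 14 past the threshold over all genes; 13 did not pass. Adjusted over the list alone, 6 members were lower and 1 higher. Wif1, at 1.34 against 2.66 FPKM, and Sfrp1, at 57.1 against 66.7 FPKM, were among the lower ones. Dkk1, a blocker of the Wnt co-receptors, was at 3.39 FPKM in null against 1.93 in controls. Frzb, the most abundant after Sfrp2, was at 86.8 against 91.0 FPKM and passed by neither adjustment. The median of the list was −0.08 (camera adjusted p = 0.00637, and adjusted p = 0.29 with an estimated correlation), and it was −0.17 without null 1, −0.14 without null 3 or wild type 2, −0.13 without heterozygote 1 and −0.19 without heterozygote 2. Target genes of Wnt/beta-catenin signalling were also lower as a group, with a median of −0.14 (camera adjusted p = 0.00529, and adjusted p = 0.558 with an estimated correlation). None of the 15 passed over all genes, with 0 higher and 0 lower; adjusted over the list alone 4 were lower and 1 higher. The lower ones included the transcription factors Sp5, at 0.74 against 1.48 FPKM, Tcf7, at 3.46 against 5.05 FPKM, and Lef1, at 2.49 against 3.55 FPKM. The higher one was the R-spondin receptor Lgr5, at 12.2 against 9.56 FPKM. The 2 most abundant targets, Ccnd1 and Apcdd1, were at 69.9 against 77.2 and 30.3 against 32.7 FPKM and passed by neither adjustment. Axin2 was at 13.0 against 13.4 FPKM, a log2 change of −0.04, and did not pass either. Of the targets 11 were below 0 in point estimate and 4 above it. Both broader Wnt lists did not pass: Wnt ligands and R-spondins, of which Wnt2 was higher and Wnt5a lower over the list alone, had a median of −0.02 (camera adjusted p = 0.891) and Wnt receptors and transducers one of 0.01 with a mean of −0.01 and a test upwards (camera adjusted p = 0.589).

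Members of the BMP pathway moved both ways. Msx1, a BMP-responsive gene, was the 1 of 24 past the threshold over all genes, and adjusted over the list alone 6 were lower and 1 higher. Besides Msx1 the lower ones included Bmp4, at 12.3 against 18.1 FPKM, and Id4, at 7.71 against 11.4 FPKM. The higher one was Bmp2, at 6.22 against 4.84 FPKM. The 2 most abundant members, Id2 and Id3, were at 103 against 93.8 and 93.3 against 95.3 FPKM. Their log2 changes were 0.13 and −0.03, and they passed by neither adjustment. The median of 0.04, the mean of −0.10 and the direction of the test differed in sign (camera adjusted p = 0.703). In the Hedgehog list 0 of 14 passed over all genes, and adjusted over the list alone Foxl1 and Hhip were higher and Foxf1 lower (median −0.02, mean 0.03, test upwards, camera adjusted p = 0.588). In the FGF list 0 of 19 passed by either adjustment, with Dusp6, a feedback phosphatase, at 56.8 against 70.2 FPKM (list median −1e-04, mean 0.03, test upwards, camera adjusted p = 0.376). The TGF-beta and activin list had 0 of 18 past the threshold over all genes and Tgfbr3 higher over the list alone, with a median of 0.05 (camera adjusted p = 0.0514). That list passed upwards under 7 alternatives over all libraries and without null 4 or wild type 1 (adjusted p = 0.0299 and 0.0345), with a range over all alternatives from 0.0162 to 0.29. In the ectodysplasin list 0 of 4 passed (camera adjusted p = 0.466).

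Cartilage genes were lower as a group. Matn4, a cartilage matrix adaptor, fell from 5.39 ± 1.24 to 2.10 ± 0.46 FPKM and Col2a1, the main cartilage collagen, from 113 ± 8.97 to 85.3 ± 3.75 FPKM; 2 of 12 passed over all genes and 10 did not. Adjusted over the list alone 6 were lower, the other 4 being the collagens Col9a1, Col9a2, Col9a3 and Col11a1. The list had a median of −0.29 (camera adjusted p = 2.23e-07, and adjusted p = 0.0805 with an estimated correlation). Of 8 osteogenic markers, Spp1, which encodes osteopontin, fell from 4.09 ± 0.29 to 2.19 ± 0.40 FPKM, and Col1a1 was at 149 against 147 FPKM. Spp1 shares 18.8% of its exons with the predicted gene Gm42793 on the same strand. Adjusted over the list alone 1 was lower, Spp1, and 1 higher, Dlx5, at 18.7 against 10.4 FPKM (list camera adjusted p = 0.803). Tooth germ markers had 0 of 5 past the threshold over all genes and Ambn, an enamel matrix gene, lower over the list alone, at 1.29 against 2.59 FPKM (list camera adjusted p = 0.122); the list passed without null 1, wild type 2 or heterozygote 2 (0.0412, 0.0496 and 0.0426), with a range over all alternatives up to 0.793.

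Cell cycle genes were slightly lower as a group, with all 23 below 0 in point estimate, a median of −0.14 and 0 past the threshold over all genes. Adjusted over the list alone 8 were lower. Among them were Pcna, the DNA polymerase clamp, at 36.5 against 41.4 FPKM, and Cdk1, the mitotic kinase, at 40.6 against 45.6 FPKM. The 2 most abundant members, Mcm6 and Top2a, were at 104 against 111 and 76.3 against 83.6 FPKM and passed by neither adjustment. The list passed (camera adjusted p = 6.53e-10) but not with an estimated correlation (adjusted p = 0.146). Cyclin-dependent kinase inhibitors and p53 targets had 0 of 11 past the threshold (median −0.05, mean 0.01, test upwards, camera adjusted p = 0.943), as did 0 of 12 immediate early and heat shock genes (camera adjusted p = 0.891). Extracellular matrix and hyaluronan genes were higher as a group, with a median of 0.13 and 0 of 26 past the threshold by either adjustment (camera adjusted p = 0.00032, and adjusted p = 0.558 with an estimated correlation). In the hypoxia and glycolysis list 1 of 15 rose, the oxygen-dependent hydroxylase gene Egln3, from 4.14 ± 0.10 to 5.87 ± 0.30 FPKM, and the list was higher with a median of 0.06 (camera adjusted p = 0.00633, and adjusted p = 0.322 with an estimated correlation). The Pax family list was lower with a median of −0.33 (camera adjusted p = 0.0211, and adjusted p = 0.322 with an estimated correlation); it contains Pax9 itself, and Pax1, the closest relative of Pax9, was at 0.34 against 1.07 FPKM and passed over the list alone. The tested genes next to Pax9 on chromosome 12 had 0 of 5 past the threshold (median −0.01, mean 0.01, test upwards, camera adjusted p = 0.803).

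**Figure D3:**
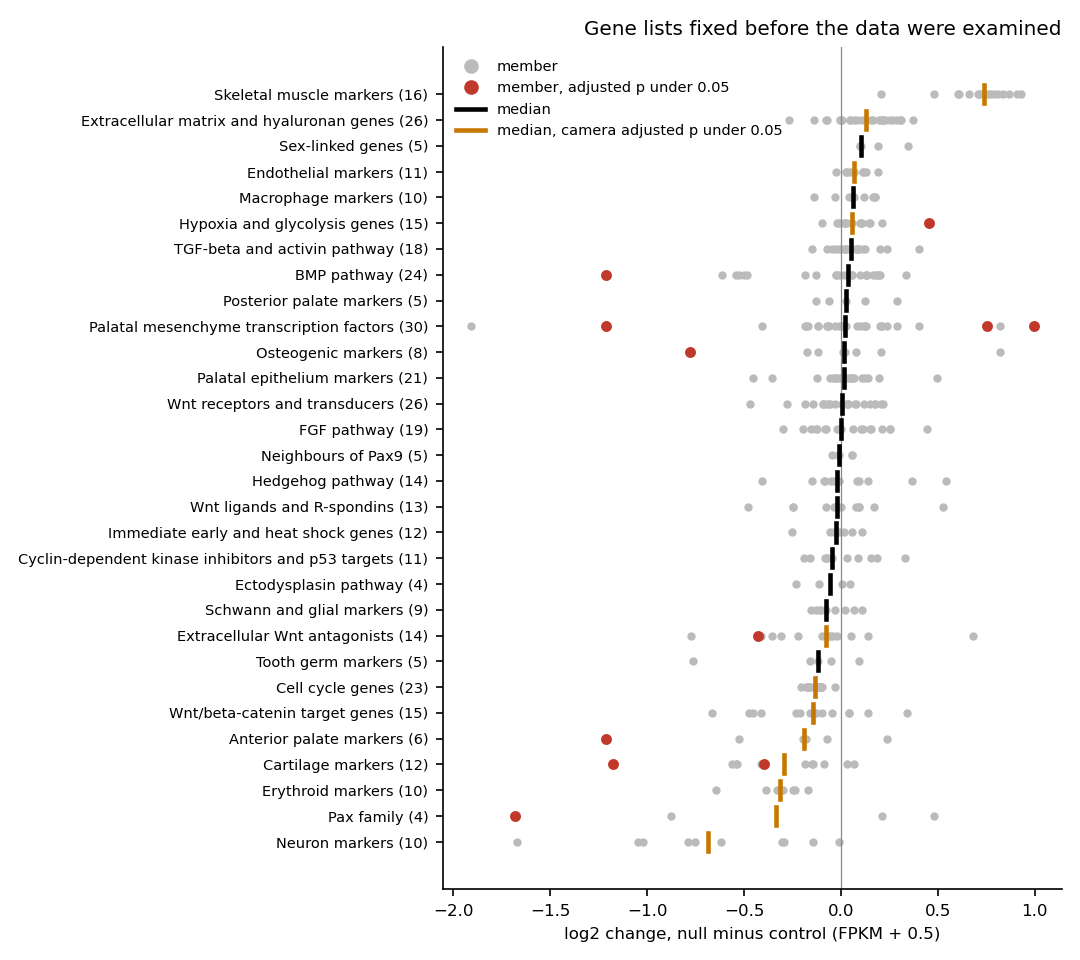
Log2 change of null minus control, on log2(FPKM + 0.5), for every tested member of 30 gene lists, with the number of tested members in parentheses; red points passed over all genes, and short bars are list medians, orange where the camera adjusted p was under 0.05. Skeletal muscle markers have the highest median at 0.74 and neuron markers the lowest at −0.69, which was −0.09 without heterozygote 2.

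Muscle and neuron markers in the dissected tissue varied widely between embryos of a genotype, with mean log2 levels within null from 1.89 to 3.59 for muscle and from 0.79 to 3.25 for neurons. Skeletal muscle markers were higher in null as a group, with a median of 0.74 (camera adjusted p = 7.78e-07, and adjusted p = 0.558 with an estimated correlation), while 0 of 16 passed singly by either adjustment. Actc1, a muscle actin, was at 82.4 ± 49.0 FPKM in null and 45.4 ± 28.5 in controls (SD, n = 4 each). Neuron markers were lower with a median of −0.69 (camera adjusted p = 0.0234, and adjusted p = 0.745 with an estimated correlation), and 0 of 10 passed over all genes. Erythroid markers were lower with a median of −0.31 and 0 of 10 past the threshold (camera adjusted p = 0.000911, and adjusted p = 0.507 with an estimated correlation), and endothelial markers were higher with a median of 0.06 and 0 of 11 (camera adjusted p = 0.0234, and adjusted p = 0.558 with an estimated correlation). Palatal epithelium markers did not pass as a group (0 of 21, camera adjusted p = 0.238), nor did macrophage (0 of 10, camera adjusted p = 0.215) or Schwann and glial markers (0 of 9, camera adjusted p = 0.891). Epithelium markers passed upwards without null 4 or wild type 1 (adjusted p = 0.0365 and 1.72e-05, up to 0.988 over all alternatives) and macrophage markers without null 1 or wild type 2 (0.034 and 0.0053, up to 0.958). The list of sex-linked genes did not pass (camera adjusted p = 0.803). It joins Xist with Y-linked genes, which move in opposite ways with sex, and its members had standard errors from 1.05 to 2.31. The test could therefore hardly show a difference in sex. Xist was above 1 FPKM in 1 null and 1 control library. In total 12 of the 30 lists passed, 4 up and 8 down; with an estimated correlation 0 passed. Leaving out 1 library ended the camera call of neuron markers without null 1, null 2, null 4, wild type 2 or heterozygote 2 (adjusted p from 0.0618 to 0.478), of endothelial markers without wild type 1, null 2 or heterozygote 1 (0.28, 0.161 and 0.136, with medians of 0.04) and of anterior palate markers without null 2 or heterozygote 1 (0.0985 and 0.0887). It also ended that of Wnt target genes without wild type 1 (0.0573), of the Pax family without wild type 2 (0.098, median −0.15) and of the hypoxia list without heterozygote 2 (0.119), where its median was −0.01. The neuron median moved to −0.09 without heterozygote 2, −0.26 without null 4, −0.33 without wild type 2 and −0.43 without null 1, and to −1.12 without wild type 1 and −1.37 without null 3. Medians of lists that stayed past the threshold moved to −0.17 for erythroid markers without wild type 2, 0.08 for extracellular matrix genes without null 2, 0.10 for endothelial markers without wild type 2, and 0.09 for the hypoxia list without wild type 1 or wild type 2. By fry for changes one way 4 passed, all of them lower: anterior palate markers, cartilage markers, cell cycle genes and the Pax family.

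The libraries also differed along a main axis, taken after the null mean and the control mean of each gene were subtracted. What is left within null and control includes any difference between wild types and heterozygotes, and the axis took up 46.2% of that variance. Null 1, null 2 and both wild types had scores from −0.41 to −0.29 on it, and null 3, null 4 and both heterozygotes from 0.12 to 0.51. Along it the skeletal muscle markers went down, with a median change of −1.54 over its length and all 16 members on that side, and the neuron markers went up with a median of 0.92. Extracellular matrix genes had a median of −0.28 along it and Wnt ligands one of −0.42. The embryos with Xist above 1 FPKM, null 4 and heterozygote 2, were at its high end with scores of 0.46 and 0.51. Because the null and control means were subtracted beforehand, the axis could not separate null from control on average. Null libraries lay on both sides of it. Among the controls it separated the wild types from the heterozygotes completely.

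**Figure D4:**
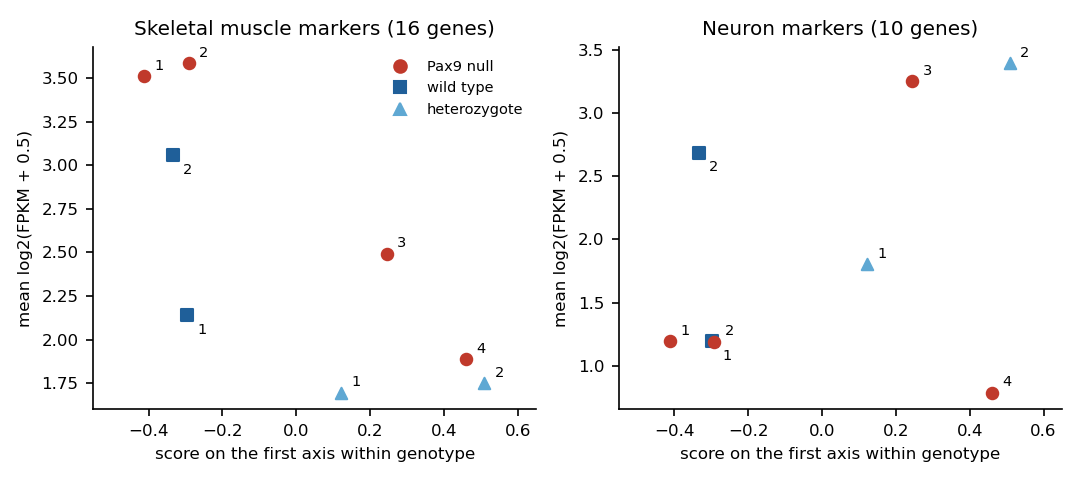
Mean log2(FPKM + 0.5) of skeletal muscle markers (16 genes, left) and neuron markers (10 genes, right) against the score on the main axis within null and control, 1 point per library. Circles are Pax9 null, squares wild type and triangles heterozygote, with the replicate number beside each. The muscle mean was 3.51 and 3.59 in null 1 and null 2 against 2.49 and 1.89 in null 3 and null 4.

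Against the wild types alone, null shelves again had lower Pax9 and Hs3st2 and higher Dlx1as and Nptx1, and in total 52 genes changed (25 higher and 27 lower, limma adjusted p under the threshold; 1571 at an unadjusted p under 0.05). Among the named genes, the largest rises were those of Stfa1, with a log2 change of 1.84, Dlx1as with 1.58, Nptx1 with 1.48, the microRNA gene Mir483 with 1.25 and Dlx6os1 with 1.15. The predicted gene Gm24899, which the rule leaves out, had a larger rise of 2.00. The Mir483 locus is short, from 142654924 to 142654996 on chromosome 7. The libraries were poly(A)-selected, so reads there need not measure the microRNA itself. The largest falls among them were those of Hs3st2 with −2.19, Pax9 with −1.76, Adcy8 with −1.73, Hs3st6, another heparan sulfate sulfotransferase, with −1.56 and Tfap2b with −1.55. Mir483 and Hs3st6 did not pass in the main comparison (limma, adjusted p = 0.349 and 0.0593). Mir483 was at 6.46 FPKM in null, 4.79 in heterozygotes and 2.51 in wild types. Osr2 had a log2 change of 0.97 (limma, adjusted p = 0.0013) and Msx1 one of −1.40 (adjusted p = 0.0298). Both wild types lay on the low side of the main axis, at −0.30 and −0.33, and null libraries lay on both sides. Null 4 held Xist above 1 FPKM and neither wild type did. In this comparison genotype is therefore partly mixed with the axis and with sex. The count was 3 without wild type 1, 16 without wild type 2, 23 without null 3, 27 without either heterozygote, 31 without null 2 and 31 among genes with a mean FPKM of at least 5; where 1 wild type was left, it was taken to vary like the other groups.

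Against the heterozygotes alone, 11 genes changed, 7 higher and 4 lower in null (limma adjusted p under the threshold; 945 at an unadjusted p under 0.05). The genes named as higher were Dlx1as with a log2 change of 1.44, Nptx1 with 1.25, Ccdc3 with 0.94, the small nucleolar RNA gene Snora24 with 0.76 and Synpo2, an actin-binding protein, with 0.65. Snora24 was at 9.30 FPKM in null and 8.69 in wild types but at 5.27 in heterozygotes, so its difference comes from the heterozygotes, which the main axis within null and control parts from the wild types. Its locus is short, from 123507937 to 123508066 on chromosome 3. The libraries were poly(A)-selected, so reads there need not measure the small nucleolar RNA itself. Hs3st2 fell by 1.93 on the log2 scale, Pax9 by 1.61, Tfap2b by 1.48 and Mpped2, a metallophosphoesterase, by 0.46. Osr2 had a log2 change of 0.54 (limma, adjusted p = 0.028), and Msx1 one of −1.02 that did not pass (adjusted p = 0.207). Both heterozygotes lay on the high side of the main axis, at 0.12 and 0.51, and null libraries lay on both sides. Genotype and axis are therefore partly mixed here as well. The count was 0 without heterozygote 1 or heterozygote 2, 6 without null 2 or null 3 and 29 after removal of the GC trend. The difference between the calls against wild type and those against heterozygotes was not tested, and both share the null libraries.

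Among changed genes, heterozygote against wild type, none was found (limma, 0 past the threshold; smallest adjusted p = 0.377; 1568 at an unadjusted p under 0.05), and limma-voom on the recovered reads also called 0, with 1637 at an unadjusted p under 0.05. Pax9 itself was at 28.1 ± 2.77 FPKM (SD, n = 2) in heterozygotes, which is 89.3% of the 31.5 ± 6.03 (SD, n = 2) in wild types, and did not differ past the threshold (log2 change −0.15, standard error 0.18, adjusted p = 0.619). Hs3st2, Tfap2b and Dlx1as had log2 changes of −0.27, −0.08 and 0.15 (adjusted p = 0.466, 0.784 and 0.487). Differences in point estimate were larger for Mir483 at 0.85, Hs3st6 at −0.71, Stfa1 at 0.64, Adcy8 at −0.52 and Osr2 at 0.43, the last with 110 against 82.0 FPKM and a standard error of 0.07, each with an adjusted p of 0.377. The main axis within null and control separated these 2 groups completely, so genotype and axis cannot be told apart in this comparison. The 1568 genes at an unadjusted limma p under 0.05 exceed the 972 of null against control. A lack of called genes therefore does not show that wild types and heterozygotes are alike. Leaving out null 1 gave 1 called gene here.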

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

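In this part the tests of sex and of muscle share for the main axis, the tests of Dlx1 and Dlx6, and the counts after removal of the GC trend were chosen only after the results were seen. For the 88 named genes and 30 lists, the gap between the farthest of the 4 null libraries and its nearest neighbour was compared with the range of the group. In 12 cases it exceeded 0.829, and chance alone marks about 1 in 20 groups. For Xist the farthest library was null 4 (0.992), the reverse of Ddx3y on the Y chromosome (0.942) and of the list of sex-linked genes (0.884), as null 4 holds Xist and lacks Y-linked RNA. Among other genes, null 2 lay apart for Kcnt2 (0.891), the glial gene Sox10 (0.852) and the macrophage gene C1qb (0.941), null 3 for Hs3st2 (0.935), and null 1 for Tfap2b (0.833) and Mir483 (0.879). Among lists, null 1 lay apart for the Hedgehog pathway (0.992) and null 3 for neuron markers (0.835) and for hypoxia and glycolysis genes (0.857).

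Among all 35 splits of the 8 libraries into 4 and 4, 2 gave at least the 57 changed genes of the real one, so chance could not be excluded by this count. The other was null 1, null 2 and both wild types against null 3, null 4 and both heterozygotes, with 4892 genes against 57, which points to a structure of the samples far larger than the genotype difference; the next highest split gave 4. These sides of the main axis are also the first 4 and the last 4 columns of the deposited table, and each holds 2 null and 2 control libraries. For changed genes, null against control, the count was 176 with the side as a block and 2 and 3 within the sides alone. After removal of the GC trend 1 of 35 splits, the real one, gave at least its 134 genes, and the highest of the others gave 44. That is the smallest share that 35 splits can give, and the removal was chosen after the first results were seen. This count therefore does not exclude chance either.

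The main axis within null and control was weighed against several sources. For sex as its whole cause, the largest gap between neighbouring libraries with Y-linked RNA was 0.414, more than the 0.215 to the nearest library without it, which argues against it. On the first axis after removal of the GC trend, libraries with Y-linked RNA lay from −0.345 to 0.172 and those without it at 0.515 and 0.566. There the gap to the nearest library without it was the larger one, so the test does not settle sex as a cause. Across genes, which are not independent replicates, the slopes along the axis followed GC content (Spearman rho −0.794 over 13418 genes), as a difference in library preparation or sequencing may produce, but the muscle part is not all GC bias, since its median slope was −1.33 after the GC trend was removed and −1.54 before. A different share of muscle alone as the whole cause is argued against, since it would move markers of all other cell types alike, while neuron markers had a median of 0.923 with a lower quartile of 0.747 and palatal mesenchyme transcription factors an upper quartile of 0.138; a first test, on erythroid markers with a median of −0.378, had not decided. Batch, dissection and stage of the embryo stay open, and none of them was tested.

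The rise of Dlx1as and Dlx6os1 was weighed against reads of the genes on the other strand. For Dlx1as this is argued against, as the log2 change of Dlx1 was 0.0061 with a standard error of 0.0633. For Dlx6os1 reads of Dlx6 cannot be told apart, because Dlx6 itself rose by 0.9948 with a standard error of 0.1422; the annotation has no exons shared between them, but it need not be complete. A change in the regulation of these Dlx loci in null embryos may remain as a hypothesis.

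DNA of another strain carried along with the mutation could change genes near Pax9. Within 10 Mb of it 1 of 50 tested genes changed, Egln3, against 54 of 13367 elsewhere (Fisher's exact two-sided p = 0.186, odds ratio 5.03 with limits of 0.123 and 30.5). With 1 gene this explanation and an effect of genotype on Egln3 cannot be told apart. Farther out on chromosome 12, Tmem30b (from 73543402) and Snapc1 (from 73964481) were called lower and Gm24899 (from 109641022) higher. A carried segment longer than this window was not tested.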

How the results depend on the processing

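The residual axis as a covariate, the side of the axis, removal of the GC trend and limma-voom were alternatives chosen after seeing the data; the others were fixed beforehand. For changed genes, null against control, 57 became 35 (18 higher, 17 lower) at a mean FPKM of at least 5, where fewer genes are tested, 268 (110 and 158) with the first residual axis as a covariate, 176 (78 and 98) with its side as a block, 134 (69 and 65) after removal of the GC trend and 171 (85 and 86) with the title number as a block as well. In the last 4 cases, 57, 57, 49 and 48 of the called genes were shared with the 57. The axis was estimated from the same values, so the p-values of its covariate and block are too small. Fewer samples gave 2 genes within null 1, null 2 and the wild types, 3 within null 3, null 4 and the heterozygotes, 0 within title number 44 (limma, 425 at an unadjusted p under 0.05; limma-voom was not run there) and 4 within 56. With the title number as a replicate block the count was 47 (17 higher, 30 lower, 40 shared); the number need not mark a pair. Under this block Osr2, Brinp3, Col2a1 and Rgs5 were not called (adjusted p = 0.0595, 0.0584, 0.0757 and 0.0879), with ranges over all alternatives of 0.000871 to 0.707, 0.0113 to 0.956, 0.00492 to 0.951 and 0.0112 to 0.814. Leaving out 1 library gave 16 to 52, lowest without wild type 1.

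For changed genes, null against wild type, the count was 31 at a mean FPKM of at least 5 and 3 to 53 over the leave-outs. For changed genes, null against heterozygote, it was 29 after removal of the GC trend, 19 with the block as well and 0 to 14 over the leave-outs, and for heterozygote against wild type 0 to 1. A lone library left in a group was assumed to vary like the others. The Pax9 level changed by −1.5765 within title number 44 (adjusted p = 0.217) and by −1.9308 within null 1, null 2 and the wild types (adjusted p = 0.0559), where fewer samples were used; its range was 0.000262 to 0.217 over all alternatives, and −1.7521 to −1.5883 in log2 change over the leave-outs. Of the gene lists, null against control, 12 passed; 0 did with an estimated correlation, 0 with that after removal of the GC trend, 4 by fry and 9 to 13 over the leave-outs. Except where samples or genes were fewer, the cause was not tested.

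Over all libraries, 1260 of 1287 values of named genes kept their side of the threshold, 18 lost it and 9 gained it; for lists these were 255 of 300, 38 and 7, the last all for the TGF-beta and activin list. Leaving out libraries, 594 of 696 values of genes kept their side and 1 gained it, the rest losing it. For lists 218 of 240 kept it, 13 lost it and 9 gained it. In parts of the libraries 239 of 348 values of genes kept it and 109 lost it. Of the named genes 59 were not called and had no call to lose. They hold most of the values that kept their side, so these shares do not show how stable the called genes were. By direction of its test no called result was reversed, though the median of the hypoxia list was −0.01 without heterozygote 2. No result outside the calls passed in the opposite direction. Changes of sign in results that stayed uncalled were not counted. No alternative reduced the depth, so what it limits was not tested.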

Other observations

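In this part the tests of Pax9 dose and of the X chromosome were chosen only after the results were seen, and the genes named here were chosen after their values were seen. Penk, the precursor of enkephalin peptides, rose from 76.9 ± 3.04 to 115 ± 5.62 FPKM (SD, n = 4 each). The protocadherins Pcdh10 and Pcdh19 and the atypical cadherin Fat4 rose by 0.48, 0.34 and 0.29 on the log2 scale. Cyp26c1, which breaks down retinoic acid, fell from 6.78 ± 0.76 to 3.98 ± 0.56 FPKM, and the neural crest factor Tfap2a fell from 5.54 ± 0.30 to 3.96 ± 0.21 FPKM. The transcription factor Hand2 was lower in every null library than in every control library but did not pass over all genes (limma, adjusted p = 0.0769).

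The mean Pax9 RNA of the 2 heterozygotes exceeded the midpoint of wild type and null, 20.2 FPKM, by 7.911 with a standard error of 2.914. An additive gene dose and a level above it cannot be told apart here, because the error rests on 2 heterozygotes and 2 wild types and the main axis parts these groups completely.

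Among the 30 risen genes with a known position, 5 lay on the X chromosome (Dcaf12l1, Nrk, Fhl1, Nexmif and Pcdh19), or 16.7% against 3.6% of the other tested genes. Fisher's exact two-sided test gave an odds ratio of 5.31 with limits of 1.58 and 14.2 and an unadjusted p of 0.00429, which adjusted by Benjamini-Hochberg over 20 chromosomes and 2 directions was 0.172. An excess of X-linked genes over chance was therefore not shown. Xist was above 1 FPKM in 1 null and 1 control library, so the groups held as many embryos with it.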
